A study of Mus musculus with 2 samples.

How the data were processed

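The samples were 2 biological replicates of H3K27me3 ChIP-seq on neural tube of mouse embryos at day 14.5 (mixed sex). Per the labels, replicate 1 was a pool of 24 embryos with 1 technical replicate and replicate 2 a pool of 34 embryos with 2 technical replicates, and the 2 pools have separate sample records. Replicates were numbered as in the labels. The sequencing instruments are named in the labels for replicate 2 only.

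The 4 peak lists on mm10 were used as deposited. Per the readme texts deposited with the samples, 1 list each was called on replicate 1 and on replicate 2 alone, 1 list was called on both replicates pooled, and the list of replicated peaks was derived from those 3 lists. The same texts name further inputs to the replicates' peak calls, in unequal number, without saying what they hold, and the rule by which a peak counted as replicated is not given in the sources used here. The aligner, the peak caller, its thresholds and the read depth are not given in the sources used here. Each peak carries a signal value, a −log10 p and a −log10 q, in the column order of the narrowPeak format in which the authors deposited the lists. What the deposited signal value is relative to is not stated, so it was used only to rank peaks within a list. The smallest deposited −log10 p was 2.00 in replicate 1, 2.05 in replicate 2 and 2.04 in the pooled list, and 43.4, 44.8, 52.8 and 67.7% of the peaks of replicate 1, replicate 2, the pooled and the replicated list had a q of at most 0.05 by the deposited −log10 q. The lists are therefore permissive at their lower end. All 15353 replicated peaks have the same coordinates in the pooled list. Peak lists give no read counts, so the depth of each sample is unknown and no interval that needs it is given. Exact binomial (Clopper-Pearson) intervals on shares of genes cover counting error only.

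Genes were taken from GENCODE release M21 and sequence from GRCm38.p6, whose chromosome lengths fit mm10. The 21938 protein-coding genes on chromosomes 1 to 19, X and Y were used. The 5' end was the start of the gene feature on its strand. The promoter was the 5' end with 1 kb on either side, and a gene was marked when a peak covered at least 1 base of it. Annotated 5' ends of some genes are those of long transcripts, which shifts their window from the promoter of shorter ones. The CpG ratio was the observed number of CpG dinucleotides divided by that expected from the C and G content of the promoter. Domains were replicated peaks joined when at most 3 kb apart. Coordinates are 1-based on mm10.

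The overlap of the replicates (at least 1 base) was tested against 1000 random circular shifts of a list within each chromosome (1-sided permutation test, smallest p 0.001), and the distribution over promoters, gene bodies and the remainder against 1000 shifts (2-sided, smallest p 0.002). Shifts move peaks into unsequenced and repetitive stretches, where no peak can be called. This lowers the shifted overlap of the replicates and the shifted shares of promoters and gene bodies somewhat, and raises the shifted share outside genes. The 22 gene lists (490 entries, all of which matched a gene) were compared with all other protein-coding genes by Fisher's exact test (2-sided) with Benjamini-Hochberg adjustment over the lists. The lists, tests, windows and alternatives were fixed before the data were examined. So was the rule for named genes, which takes the 15 longest domains with up to 4 genes each, the 20 genes with the highest signal value of a replicated peak at the promoter, and up to 4 marked members of each list by most promoter bases covered. For unmarked members it takes all where there are at most 5, and otherwise the first 4 by name. It also takes the 8 genes marked in replicate 1 only and the 8 marked in replicate 2 only with the highest signal value.

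The alternatives fixed at that stage were a promoter window of 2.5 kb on either side, at least 500 covered bases, the upper 50% of peaks by signal value, any annotated transcript start, the pooled list, the list of each replicate alone, 10000 random gene lists matched on promoter CpG decile, overlap of at least 50% of a peak, equal numbers of peaks, ranking by −log10 q, and merging distances of 1 and 10 kb. Peaks with q of at most 0.05 only, and genes marked in both replicates' own lists, were added after the data were seen. The code was tested on simulated data. With 50% of 22407 peaks copied from the other list, 50.5% were found to overlap, 0 of 20 pairs of independent lists had a permutation p under 0.05, and 3 of 100 random gene lists among 21938 genes had an unadjusted p under 0.05 in Fisher's exact test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with a random seed of 1.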

Results

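Trimethylation of lysine 27 on histone H3 (H3K27me3), the mark that Polycomb repressive complex 2 places on silent developmental genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the neural tube of mouse embryos at day 14.5. The neural tube is the embryonic tissue that gives rise to the brain and spinal cord, and the labels do not say which level of it was taken. The series had 1 group with 2 biological replicates, a pool of 24 embryos (replicate 1) and a separate pool of 34 embryos (replicate 2), both of mixed sex. No other age, tissue or mark was analysed here, so no comparison between conditions was made. The peak list of replicate 1 held 32140 peaks over 12.5 Mb and that of replicate 2 held 22407 peaks over 8.11 Mb. The list called on both replicates together held 21571 peaks over 11 Mb, and the list of replicated peaks held 15353 peaks over 9.34 Mb (0.343% of the genome). Median peak lengths were 281, 269, 334 and 423 bases in the same order. The lists give no read counts, so the depth behind each peak is unknown. A protein-coding gene is called marked here when a replicated peak overlaps the 2001-base window centred on its 5' end. By this rule 2361 of 21938 genes (10.8%) were marked, and 1402 with at least 500 covered bases, 1508 with the upper 50% of peaks by signal value and 5751 with the list of replicate 1 alone. Tests on genes compare one class of genes with another within this peak set. Genes are not biological replicates, and neighbouring genes can share a peak. A gene called unmarked by the replicated list can still have a peak in a replicate's own list.

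The transcription factors that pattern the neural tube and specify its neurons were marked almost throughout. The lists come from dissected tissue of pooled embryos, so they do not show in which cells a promoter was marked. Expression was not measured, and a marked gene may have been active in other cells of the same sample. Of 30 factors of the progenitor domains, 28 were marked (93.3%, 95% exact binomial interval 77.9 to 99.2%), against 10.6% of all other genes. Olig1, a factor of the ventral motor neuron and oligodendrocyte progenitors (chromosome 16, 91269772 to 91271933), had all 2001 bases of its window covered, with a signal value of 7.32. The window of Foxn4, a factor of V2 interneuron progenitors, was also covered over its full length. Neurog1, a proneural factor of the dorsal neural tube, had 1953 bases covered, and Ptf1a, a determinant of dorsal inhibitory neurons, had 1950 bases covered. The unmarked members were Ascl1, a proneural factor, and Gli2, an effector of hedgehog signalling. Ascl1 had 308 bases covered in the list of replicate 1 and none in that of replicate 2, and Gli2 had none in either.

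Factors of motor neurons and interneurons were marked in 29 of 30 cases (96.7%, interval 82.8 to 99.9%). Mnx1, a motor neuron determinant (chromosome 5, 29473034 to 29478470), had 1686 bases covered. Phox2a, a factor of noradrenergic and visceral motor neurons, had 1916 bases covered, Tlx1, a factor of dorsal excitatory neurons, 1715 bases, and Barhl2, a factor of commissural interneurons, 1668 bases. Foxp1, which marks limb-innervating motor neurons, was the only unmarked member. Regional factors of the forebrain and midbrain were marked in 25 of 26 cases (96.2%, interval 80.4 to 99.9%). Six3, a factor of the anterior forebrain (chromosome 17, 85613608 to 85629302), had all 2001 bases covered, Fezf2, a factor of subcerebral projection neurons, 1931 bases, Vax2, a factor of the ventral eye, 1808 bases, and Dlx6, a factor of forebrain inhibitory neurons, 1753 bases. Hesx1, an early factor of the anterior forebrain and pituitary, was the only unmarked member. Counting any annotated transcript start, 100% of this list was marked.

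Factors of other germ layers and signalling ligands were also marked more often than other genes. Mesoderm and muscle factors were marked in 25 of 30 cases (83.3%, interval 65.3 to 94.4%), among them Tbx1 and the notochord factor T with all 2001 bases covered, the myogenic factor Myod1 with 1874 bases and Tcf21 with 1872 bases. The unmarked members were Meox1, Mesp2 and the myogenic factors Myf5, Myf6 and Myog. In the own lists of replicates 1 and 2, Meox1 had 257 and 196 bases covered and Mesp2 234 and 298 bases. Myf5 had 420 bases covered in replicate 1 only, and Myf6 and Myog had none in either. Endoderm and heart factors were marked in 17 of 20 cases (85.0%, interval 62.1 to 96.8%). Hhex had 2001 bases covered, the cardiac and endodermal factor Gata4 1761 bases, Cdx2 1752 bases and Cdx1 1592 bases, while Hnf1a, Hnf4a and Prox1 were unmarked. Of 19 Wnt ligands, 16 were marked (84.2%, interval 60.4 to 96.6%), with Wnt9a, Wnt10a, Wnt1 and Wnt2 the most covered (2001, 1955, 1926 and 1795 bases), and Wnt4, Wnt8a and Wnt8b unmarked. Of 20 BMP, GDF and hedgehog ligands, 13 were marked (65.0%, interval 40.8 to 84.6%). They included Shh, the ventral patterning signal (1814 bases), Gdf7, a roof plate signal (1590 bases), Ihh (1489 bases) and Bmp8a (1438 bases), and the unmarked ones included Bmp10, Bmp5, Gdf1 and Gdf11. FGF ligands were marked in 7 of 22 cases (31.8%, interval 13.9 to 54.9%), with Fgf3, Fgf17, Fgf8 and Fgf16 the most covered (1663, 1529, 1480 and 1465 bases), and Fgf1, Fgf10, Fgf11 and Fgf12 among the unmarked. Counting any annotated transcript start, 54.5% of the FGF ligands were marked.

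Transmitter identity, neural crest, endothelial, glial, imprinted and cell cycle inhibitor genes were marked more often than other genes, and the lists were not tested against one another. Transmitter and neuropeptide identity genes were marked in 13 of 22 cases (59.1%, interval 36.4 to 79.3%). The cholinergic pair Slc18a3 and Chat had 1841 and 1718 bases covered, the glutamate transporter gene Slc17a7 1791 bases and the dopamine transporter gene Slc6a3 1588 bases. Calca, Dbh, Gad1 and Gad2 were among the unmarked, although Gad2 had 799 bases covered in the list of replicate 2 and Calca 211 in that of replicate 1. Neural crest, ganglion and pigment cell genes were marked in 9 of 20 cases (45.0%, interval 23.1 to 68.5%), led by Prdm12, Ntrk1, Erbb3 and Pou4f1 (1764, 1575, 1528 and 1380 bases), with Dbh, Dct, Mitf and Mpz among the unmarked. Endothelial and connective tissue genes were marked in 9 of 18 cases (50%, interval 26.0 to 74.0%), led by Cldn5, Kdr, Sox18 and Foxc1 (1877, 1671, 1435 and 1364 bases), with Acta2, Cdh5, Col3a1 and Dcn among the unmarked. Glial genes were marked in 5 of 16 cases (31.2%, interval 11 to 58.7%), led by Gjb6, Sox10, Pdgfra and Cspg4 (1557, 1327, 479 and 387 bases), with Aldh1l1, Aldoc, Aqp4 and Cnp among the unmarked (12.5% with at least 500 covered bases). Imprinted genes were marked in 8 of 24 cases (33.3%, interval 15.6 to 55.3%), led by Kcnq1, Ascl2, Grb10 and Igf2 (1688, 1642, 1517 and 1235 bases), with Cdkn1c, Igf2r, Impact and Magel2 among the unmarked. Cell cycle inhibitor genes were marked in 3 of 7 cases (42.9%, interval 9.90 to 81.6%). These were Cdkn2a (2001 bases), Cdkn2b (1731 bases) and Cdkn2c (648 bases), all inhibitors of the cyclin D kinases, and Cdkn1a, Cdkn1b, Cdkn1c and Cdkn2d were unmarked (14.3% with the upper 50% of peaks).

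The other 7 lists did not pass the threshold in either direction, and the pan-neural progenitor list lay close to it. Pan-neural progenitor genes were marked in 5 of 18 cases (27.8%, interval 9.69 to 53.5%), including Pax6, Sox1, Hes5 and Sox2 with 1241, 1040, 944 and 709 bases covered, and not Dll1, Fabp7, Hes6 or Mki67. In the list of replicate 1 alone 13 of the 18 (72.2%) had a peak, Dll1 (138 bases) and Mki67 (314 bases) among them, and with the upper 50% of peaks 16.7% were marked. Pan-neuronal genes were marked in 3 of 18 cases (16.7%, interval 3.58 to 41.4%). These were Stmn3, Elavl3 and Ina, with 345, 230 and 184 bases covered, and none of them was marked in the list of replicate 2 or over 500 bases. The share was 38.9% in the list of replicate 1 alone and 5.56% with the upper 50% of peaks or with q of at most 0.05. Dcx, Elavl4, Gap43 and Map2 were among the unmarked. Of 25 housekeeping genes only Vcp was marked (4.00%, interval 0.101 to 20.4%), with 332 bases covered, and Actb, Chmp2a, Eef1a1 and Eef2 were among those that were not. In the list of replicate 1, 10 of the 25 had a peak, and in that of replicate 2 none had. None of 18 germline genes was marked (upper exact limit 18.5%), Brdt, Dazl, Ddx4 and Hormad1 among them. Blood cell genes were marked in 3 of 18 cases (16.7%, interval 3.58 to 41.4%), namely Ikzf1 (1892 bases), Tal1 (1050 bases) and Gfi1b (354 bases), with Alas2, Cd3e, Csf1r and Gata1 among the unmarked. Differentiated genes of other organs were marked in 3 of 24 cases (12.5%, interval 2.66 to 32.4%), namely Nphs2 (1429 bases), Ckm (1071 bases) and Nphs1 (225 bases), and the liver genes Afp, Alb, Apoa1 and Apoa2 were unmarked. Genes of Polycomb complexes and H3K27 demethylases were marked in 4 of 26 cases (15.4%, interval 4.36 to 34.9%). These were Pcgf5, Phf19, Cbx4 and Cbx8 (1284, 792, 235 and 117 bases), while Aebp2, Bmi1, Cbx2 and Cbx6 were among the unmarked. In the list of replicate 1 alone 13 of the 26 (50%) had a peak, Bmi1 (309 bases) and Cbx6 (271 bases) among them, and the share was 26.9% in the pooled list and 7.69% with at least 500 covered bases.

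**Figure D1:**
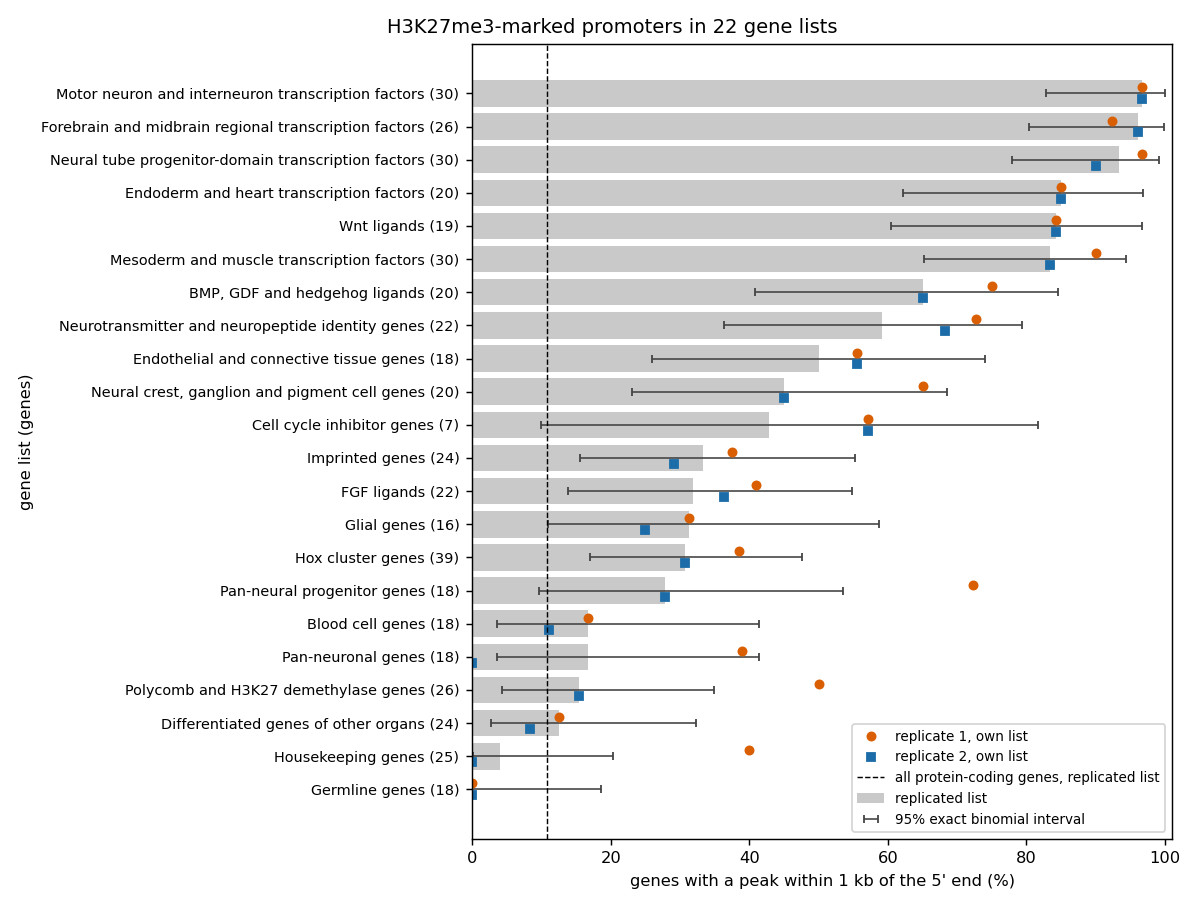
Percentage of genes in each of 22 gene lists with an H3K27me3 peak within 1 kb of the 5' end (x axis); the number of genes stands in brackets beside each list. Grey bars are the replicated list with 95% exact binomial intervals, orange circles and blue squares are the lists of replicates 1 and 2, and the dashed line is the share over all protein-coding genes (10.8%); motor neuron and interneuron factors stand at 96.7% and germline genes at 0%.

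By Fisher's exact test (2-sided, Benjamini-Hochberg adjusted over the 22 lists), 15 lists were marked more often than the other genes and 0 less often. Adjusted p was 4.27e-26 for motor neuron and interneuron factors, 2.61e-24 for progenitor-domain factors, 9.58e-23 for forebrain and midbrain factors and 2.56e-19 for mesoderm and muscle factors in Fisher's exact test. It was 1.21e-13 for endoderm and heart factors, 8.00e-13 for Wnt ligands, 2.96e-08 for BMP, GDF and hedgehog ligands and 1.35e-07 for transmitter identity genes in the same exact test. The remaining exact test values below the threshold were 9.15e-05 (endothelial), 0.000233 (neural crest), 0.00114 (Hox), 0.00491 (imprinted), 0.0111 (FGF), 0.0358 (glial) and 0.0458 (cell cycle inhibitors). The exact test values above it were 0.0512 (pan-neural progenitor), 0.323 (germline), 0.502 (pan-neuronal and blood), 0.543 (Polycomb and housekeeping) and 0.739 (other organs). Some lists share genes, so their tests are not independent. Of the 9 marked neural crest genes, Foxd3, Phox2b and Pou4f1 are also in the motor neuron and interneuron list, Prdm12 is in the progenitor-domain list and Sox10 in the glial list. Alternatives ended 5 of these calls, by adjusted p in the same exact test. The list of replicate 1 alone ended the Hox (0.146), glial (0.582), FGF (0.197), imprinted (0.282) and cell cycle inhibitor (0.129) calls. The glial call also ended with the 2.5 kb window (0.0684), at least 500 covered bases (0.375), any annotated transcript start (0.0596), the list of replicate 2 alone (0.0842) and genes marked in both replicates (0.0562), all by the exact test. The Hox call also ended with at least 500 covered bases (exact test 0.0527), and the cell cycle inhibitor call with the 2.5 kb window (0.0712), the upper 50% of peaks (0.487) and CpG-matched random lists (permutation 0.145). Pan-neural progenitor genes passed the threshold in the exact test with at least 500 covered bases (0.0388), any annotated start (0.0294), the pooled list (0.0125), replicate 2 alone (0.0359), replicate 1 alone (0.000143) and genes marked in both (0.0229). Among the alternatives in which they did not pass were the 2.5 kb window (exact test 0.0948) and the upper 50% of peaks (exact test 0.179). Against CpG-matched random lists they did not pass either (27.8 against 14.8%, adjusted permutation p 0.249). In the list of replicate 1 alone, Polycomb genes were marked more often (exact test 0.0202) and germline genes less often (0.0122) than other genes.

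In the Hox clusters, whose genes set position along the body axis, the mark lay at one end. Of 39 Hox genes 12 were marked (30.8%, interval 17.0 to 47.6%), and 15.4% with at least 500 covered bases and 17.9% with the upper 50% of peaks. Of these, 11 belonged to paralog groups 10 to 13, the posterior groups, which hold 12 genes, and 1 belonged to groups 1 to 9, which hold 27 genes. The most covered were Hoxc13 (chromosome 15, 102921103 to 102928814; 1370 bases), Hoxb13 (1331 bases), Hoxd12 (1287 bases) and Hoxc12 (904 bases). Hoxa1, Hoxa2, Hoxa3 and Hoxa4 were among the unmarked. The exceptions, named after their values were seen, were Hoxd10, the unmarked gene of groups 10 to 13, and Hoxd1, the marked gene of groups 1 to 9. Replicated peaks covered 30.4% of the span of Hoxa10 to Hoxa13 (chromosome 6, 52231197 to 52260880) and none of the span of Hoxa1 to Hoxa9 (chromosome 6, 52155590 to 52231089). They covered 94.3% of the Hoxb13 gene and none of the span of Hoxb1 to Hoxb9. In the Hoxc cluster they covered 43.8% of the span of groups 10 to 13 against 1.04% of that of groups 4 to 9, and in the Hoxd cluster 45.8% against 1.27%. The split held in both replicates, with 11 of 12 genes of groups 10 to 13 marked in each and 4 and 1 of 27 genes of groups 1 to 9 marked in replicates 1 and 2. The split into paralog groups was chosen after the values were seen, and Fisher's exact test (2-sided) gave p = 8.31e-08 for it. The 39 genes lie in 4 clusters, and marked neighbours shared domains, as Hoxa10, Hoxa11 and Hoxa13 did. They are not independent units, so this p overstates the evidence for the split. The spans of the Hoxc genes overlap by a few kb where long transcripts of Hoxc5 begin near Hoxc10.

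**Figure D2:**
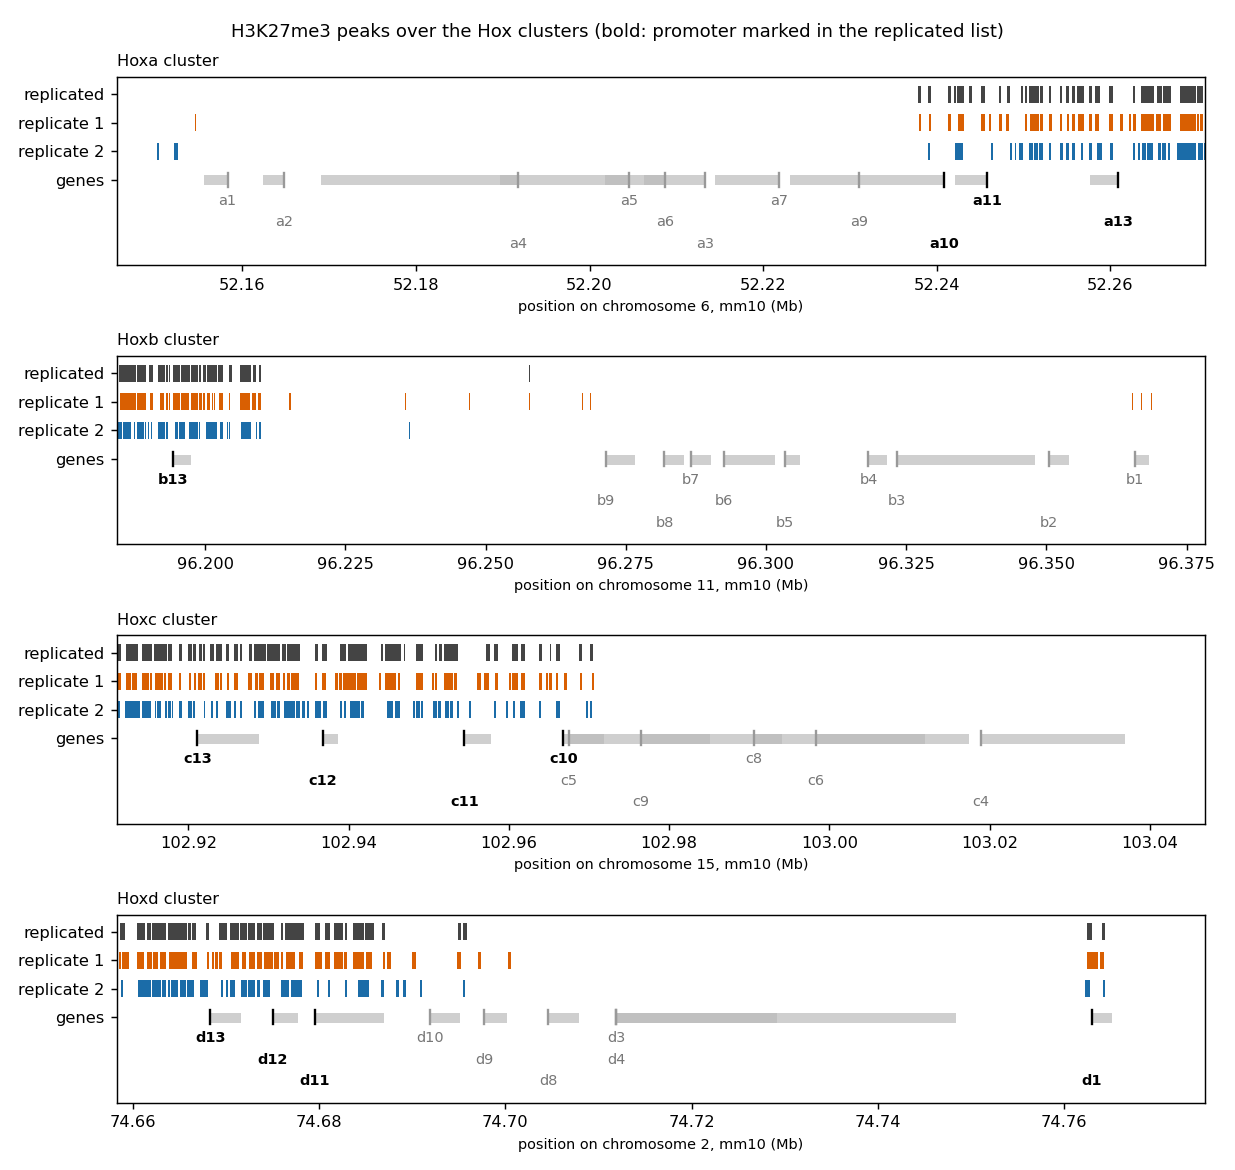
H3K27me3 peaks over the 4 Hox clusters, with the position on each chromosome in Mb of mm10 on the x axis and 1 row each for the replicated list (grey), replicate 1 (orange), replicate 2 (blue) and the genes (grey boxes, with a tick at the 5' end). Names in bold are marked in the replicated list: 11 of the 12 genes of groups 10 to 13, and Hoxd1.

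The longest domains of the mark included the posterior ends of all 4 Hox clusters and the region of Dbx1. Joining replicated peaks at most 3 kb apart gave 4951 domains with a median length of 1114 bases, of which 2348 (47.4%) were single peaks. Domains of at least 10 kb numbered 327. They held 33.4% of the replicated peaks, and 238 of them contained the 5' end of a protein-coding gene, 281 genes in all. The longest spanned 112 kb on chromosome 7 (49614641 to 49726191), with 82 peaks covering 66.4% of it, and contained the 5' end of Dbx1, a factor of V0 interneuron progenitors. It was followed by 59.3 kb around Dmbx1, a midbrain and hindbrain homeobox gene (chromosome 4, 115926198 to 115985455), and 49.6 kb around Hoxc13 and Hoxc12 (chromosome 15, 102903981 to 102953587). Other domains among the 15 longest contained Cdkn2a and Cdkn2b (48.4 kb), Tbx3 (48.0 kb), Hand2 (47.9 kb), Hoxb13 (45.1 kb), Hoxa10, Hoxa11 and Hoxa13 (43.6 kb), Evx2, Hoxd13, Hoxd12 and Hoxd11 (43.4 kb), Lhx2 (41.2 kb), Olig2 (41.2 kb) and Nkx2-1 (41.0 kb). The other 3 of the 15 contained no protein-coding 5' end. One of 49.2 kb (chromosome 12, 56442012 to 56491166) ended 45.7 kb from the 5' end of Nkx2-1. One of 44.4 kb (chromosome 17, 85449000 to 85493408) overlapped the gene body of Camkmt and lay 120 kb from the 5' end of Six3, and one of 41.7 kb (chromosome 5, 101507940 to 101549629) lay 115 kb from the 5' end of Nkx6-1. The domain counts depend on the merging distance, with 173 domains of at least 10 kb at 1 kb, the longest of 45522 bases, and 544 at 10 kb. The upper 50% of peaks by signal value gave 3001 domains, of which 201 reached 10 kb, and the kinds of gene in the long domains were not tested. The replicates' own lists gave 8424 domains in replicate 2 and 14195 in replicate 1, of which 331 and 431 reached 10 kb.

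The strongest peaks that overlapped a promoter window lay at genes of several kinds, led by Klf14, Olig1 and Fgf8. The highest signal value of a replicated peak at a promoter, 8.83, was that of Klf14 (chromosome 6, 30956023 to 30959078), a zinc-finger gene without introns. Olig1 (7.32), the growth factor gene Fgf8 (6.88) and the homeobox gene Irx4 (6.78) followed. Dlgap2, which encodes a postsynaptic scaffold protein, had 6.47. The neighbouring retinoic acid hydroxylase genes Cyp26a1 and Cyp26c1 lay in one domain of 22.6 kb and had 6.23 each, as had Helt, Lhx2, Nkx2-4 and Tbx4. Gata4 and the cardiac sodium channel gene Scn5a had 6.12, the lymphoid factor gene Ikzf3 as well as Rprml and Tmem200b 6.01, and Adra2c, Irf4, Mmp23 and Slc22a3 5.90. All 20 of these genes were also marked in both replicates' own lists. An overlap of 1 base with the window was enough for a peak to count. The peaks behind the values of Fgf8 (chromosome 19, 45743884 to 45745562) and Cyp26a1 (37692641 to 37696868) lay almost wholly outside the window. Their values need not describe the promoter itself, although 1480 and 1942 bases of these windows were covered in all. The signal values are the authors' and rank peaks within a list only.

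Marked promoters were rich in CpG dinucleotides. Among promoters ranked by the ratio of observed to expected CpG and divided into 4 classes of equal size, 0.820, 9.79, 17.3 and 15.1% were marked in the replicated list, from the lowest class to the highest. The difference between the highest and the lowest class was 14.3 percentage points (odds ratio 21.5, p = 1.29e-200, Fisher's exact test, 2-sided). It was 7.71 points with at least 500 covered bases, 8.70 with the upper 50% of peaks, 9.39 with genes marked in both replicates, 9.70 with the list of replicate 2 alone and 47.7 with that of replicate 1 alone. Unmarked genes such as Gad1 (ratio 0.291), Col3a1 (0.154) and Apoa1 (0.167) had CpG-poor windows at the annotated 5' end. Marked genes with low ratios there also occurred, among them Gata4 (0.199), Igf2 (0.171) and Nphs1 (0.201). Annotated 5' ends of long transcripts can lie away from the promoters of shorter ones, so these ratios need not describe every promoter of a gene. Of 2 housekeeping promoters with similar ratios, that of Eef2 (0.691) was unmarked and that of Vcp (0.695) was marked. The strongest peaks at Vcp and Nphs1 were weak (−log10 q of 0.508 and 0.687), and neither promoter had covered bases in the list of replicate 2. The replicates parted in the CpG-rich classes. In the highest decile 54.2% of promoters were marked in the list of replicate 1 and 8.07% in that of replicate 2, whereas in the fifth decile the values were 28.7 and 17.5%.

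**Figure D3:**
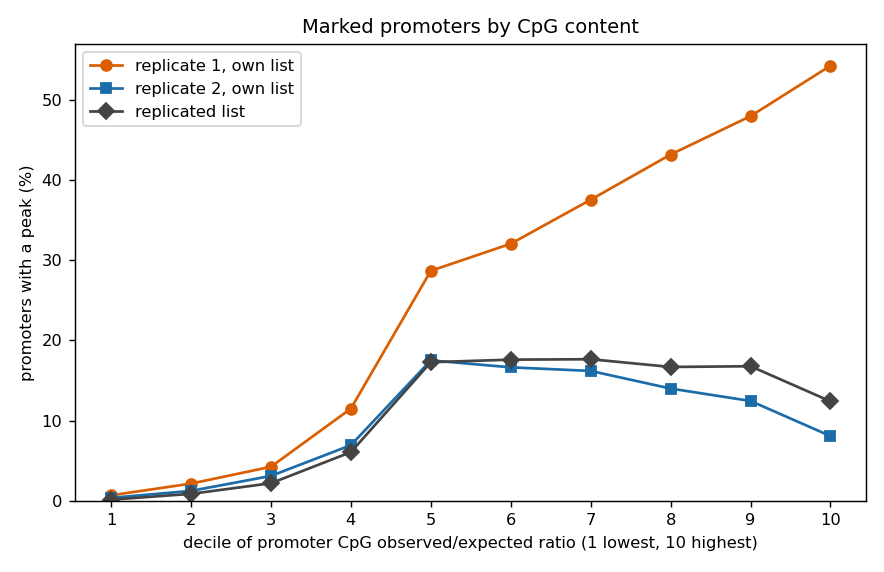
Percentage of protein-coding promoters with a peak (y axis) in each decile of the promoter CpG observed/expected ratio (x axis, 1 lowest to 10 highest), for replicate 1 (orange circles), replicate 2 (blue squares) and the replicated list (grey diamonds). Replicate 1 reaches 54.2% in decile 10, where replicate 2 is at 8.07% and the replicated list at 12.4%.

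Over the genome, 3805 of 15353 replicated peaks (24.8%) overlapped a protein-coding promoter, against a mean of 2.17% when the peaks were shifted along their chromosomes, an 11.4-fold ratio. Gene bodies outside promoters held 39.5% of peaks, against 39.6% when shifted. Within them, peaks touching an exon made up 15.8% of all peaks (7.06% shifted) and peaks in introns alone 23.8% (32.5% shifted). The remaining 35.7% lay outside protein-coding genes, against 58.2%. The permutation test by 1000 shifts (2-sided) gave p = 0.002, the smallest it can give, for promoters, exons, introns and the remainder, and the permutation p was 0.991 for gene bodies as a whole. With promoter windows of 2.5 kb on either side, gene bodies held 29.0% of peaks, fewer than when shifted (permutation p = 0.002, the smallest possible).

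Most genes marked in replicate 2 were marked in replicate 1, and most genes marked in replicate 1 were not marked in replicate 2. Of the 2116 genes marked in the list of replicate 2, 1858 (87.8%) were also marked in that of replicate 1. Replicate 1 marked 5751 genes (26.2%), so that 3893 genes were marked in replicate 1 only and 258 in replicate 2 only. Genes marked in both had a median of 879 promoter bases covered in replicate 1 and 581.5 in replicate 2, and genes marked in replicate 1 only had 288 in replicate 1. Broad coverage in replicate 1 only also occurred, as at Plekhd1 (1407 bases), Fam83b (805 bases) and Gca (735 bases). The genes of replicate 1 only with the highest signal were Tc2n (5.49), 1500011B03Rik, Dock9 and Fam83b (5 each), Gca, Map2k2 and Plekhd1 (4.83 each) and 1700066B19Rik (4.67). Of these, Map2k2 and 1700066B19Rik were not marked in the replicated list. Those of replicate 2 only were Trim7 (5.81), Syce2 (5.53), Slc47a2 (5.08), the splicing regulator gene Rbfox1 and Tns1 (4.95 each), Ckmt1 (4.90), Nt5e (4.87) and the hedgehog antagonist gene Hhip (4.74), of which Hhip was not marked in the replicated list.

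Of the peaks of replicate 1, 36.4% overlapped a peak of replicate 2 by at least 1 base, against a mean of 0.608% and a highest value of 1.55% over 1000 shifts. Of the peaks of replicate 2, 57% overlapped a peak of replicate 1, against 0.919 and 4.17%. The covered bases in common, 4.31 Mb, were 26.4% of the bases covered in either replicate, against 0.204% when shifted. All 3 permutation tests (1-sided) gave p = 0.001, the smallest they can give. Overlap rose with signal value over 4 classes of equal size within each list. It was 67.5% in the highest and 21.7% in the lowest class of replicate 1 (odds ratio 7.49), and 84.3 and 40.9% in those of replicate 2 (odds ratio 7.76), with log10 p of -772 and -515 in Fisher's exact test (2-sided). The peaks of the highest classes were longer (medians of 483 and 453 bases) than those of the lowest (236 and 220 bases), which adds to their chance of overlap. Many neighbouring peaks lie in the same domain and are not independent, so these exact test values overstate the evidence. Of the replicated peaks, 63.9% overlapped peaks of both replicates' own lists, 25.1% those of replicate 1 only, 7.91% those of replicate 2 only and 3% neither. With 2 replicates of 1 group these values describe this pair of libraries and carry no estimate of the spread between embryos.

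**Figure D4:**
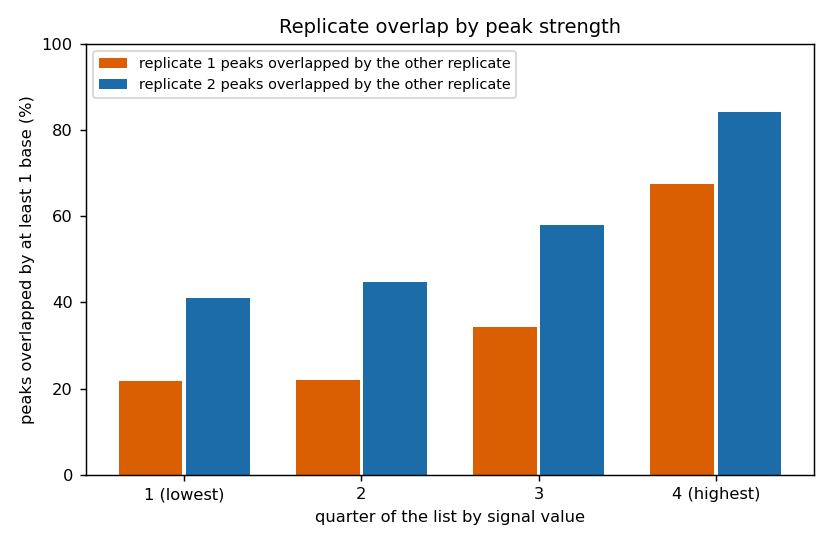
Percentage of peaks overlapped by at least 1 base by a peak of the other replicate (y axis), in 4 equal classes of each list by signal value (x axis, lowest to highest), for replicate 1 (orange) and replicate 2 (blue). Overlap is 21.7 and 40.9% in the lowest classes and 67.5 and 84.3% in the highest.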

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

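Peaks with q of at most 0.05 and genes marked in both replicates' own lists were alternatives chosen after the data were seen. Under every alternative the progenitor-domain, motor neuron and interneuron, forebrain and midbrain, mesoderm, endoderm and heart, Wnt, BMP, transmitter identity, endothelial and neural crest lists were marked more often than other genes, and the replicates overlapped more than when shifted. The number of lists marked more often ran from 12 to 16. The number of marked genes was 1402 with at least 500 covered bases, 1508 with the upper 50% of peaks by signal value, and 2116 to 5751 with 1 replicate's list alone. Domains of at least 10 kb numbered 173 and 544 at merging distances of 1 and 10 kb. With the upper 50% of peaks there were 3001 domains, 201 of at least 10 kb, and with 1 replicate's list 8424 to 14195 domains. By construction, the upper 50% left 16070, 11203, 10785 and 7676 peaks in the lists of replicate 1, replicate 2, the pooled and the replicated list, which covered 7.92 (replicate 1), 5.07 (replicate 2) and 6.15 Mb (replicated). The share of peaks in gene bodies was 29.0% with the wide promoter window, which takes peaks from the gene body class, and below the shifted value. It was 39.5% in the pooled list and 38.3 to 41.1% in the replicates' lists, on either side of the shifted values and within their spread. The difference from other genes, in percentage points, changed sign for 4 lists, all above the threshold in the main exact test. Pan-neuronal genes stood at -6.40 with at least 500 covered bases, -1.32 with the upper 50% of peaks, -2.65 at q of at most 0.05, -8.48 with genes marked in both replicates and -9.65 to 12.7 with 1 replicate's list. Genes of other organs stood at -1.45 in the pooled list, -0.136 with genes marked in both and -13.7 to -1.31 with 1 replicate's list. With 1 replicate's list blood cell genes stood at -9.56 to 1.47 and housekeeping genes at -9.66 to 13.8. The cause was not tested for any of these. Over the gene lists, 187 other values kept direction and side of the threshold. The 14 that lost it were of the glial, cell cycle inhibitor, Hox, FGF and imprinted lists. The 8 that passed it were 6 of the pan-neural progenitor list and, with replicate 1's list, the Polycomb (more often marked) and germline (less often marked) lists. No paired analysis was possible because there was only 1 group. Unknown depth limits how the unequal numbers of peaks in the replicates can be read.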

Other observations

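The gene families, non-coding genes and tests in this part were chosen after the marking of the gene lists had been seen, the test of the peak calling threshold in the Hox clusters was written after its result had been seen, and the test of active promoters on 4 gene lists was chosen after their shares in replicate 1 had been seen. The 24 families, taken by gene symbol, were each compared with all other genes and not with one another. All 8 Lhx, 6 Dlx and 6 Irx genes were marked, as were 13 of 14 Nkx genes (all but Nkx6-3), 8 of 9 Pax genes (all but Pax4) and 5 of 6 Gata genes (all but Gata1). Of 44 Fox genes 27 were marked (61.4%), including Foxj1, Foxg1 and Foxa1 but not Foxo3 or Foxk2, and of 19 Sox genes 10, including Sox17, Sox10 and Sox21 but not Sox4, Sox9 or Sox11. Of 365 zinc-finger genes named Zfp, 9 were marked (2.47%) against 10.9% of other genes (adjusted p = 9.21e-09, Fisher's exact test over the 24 families, 2-sided). In the replicates' own lists 60 (16.4%, replicate 1) and 5 (1.37%, replicate 2) were marked, against 26.2 and 9.65% of all genes. None of 1093 olfactory receptor (Olfr) genes and none of 327 vomeronasal receptor (Vmn) genes was marked in the replicated list. Marked members of other families were 34 of 92 potassium channel genes (37.0%), 11 of 26 glutamate receptor genes (42.3%) and 6 of 9 adrenergic receptor genes.

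Among non-coding genes, 255 of 2959 antisense genes (8.62%) and 189 of 5854 lincRNA genes (3.23%) had a replicated peak within 1 kb of the 5' end, and 73.3 and 47.6% of these lay within 10 kb of the 5' end of a marked protein-coding gene. Non-coding genes of these and other types beside marked regulators, with covered bases, included Hotair (550 bases covered) between Hoxc12 and Hoxc11, Hottip (615) beside Hoxa13, Hoxa11os (749), Evx1os (1591), Six3os1 (1315), Hand2os1 (1265), Wt1os (1238) and Dlx6os1 (1182). Hotairm1 in the anterior Hoxa cluster, Meg3, H19, Xist, Malat1, Rmst, Pantr1 and Sox2ot had no covered bases, although Sox2, which lies within Sox2ot, was marked.

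The first pattern weighed is the excess of promoters marked in replicate 1 only (3893) over replicate 2 only (258). The larger number of peaks in replicate 1 accounts for part of it at most, and leaving out weak peaks did not remove it. At q of at most 0.05 there were 9.48 times as many genes in replicate 1 only as in replicate 2 only (1963 against 207). Called peaks cannot show signal of replicate 2 that fell below its own calling threshold, so how far the threshold contributes stays undecided. The second test counted all marked genes, not those of 1 replicate only. With equal numbers of peaks replicate 1 marked 2.16 times as many genes as replicate 2 (4577 against 2116), and with its full list 5751. Fragments of open, active promoters were tested at ribosomal protein and proteasome genes. Of those that replicate 2 did not mark, replicate 1 marked 24.8%, against a mean of 32.8% in CpG-matched lists (permutation p = 0.981, 1-sided). The predicted excess over genes of like CpG content was thus absent. The matched genes can themselves have active promoters, because expression was not measured, so the test cannot exclude the explanation. At other active genes the test decides nothing, because its pan-neural progenitor, pan-neuronal, housekeeping and Polycomb lists were picked for their shares in replicate 1. Together these stood at 45.2%, against 32.4% in CpG-matched lists (permutation p = 0.0104, 1-sided). Each lay above its matched mean, in the same order 61.5 against 28.5%, 38.9 against 26.3%, 40 against 32.8% and 45.5 against 39.5%. Taken singly, the permutation p (1-sided) was 0.0079, 0.154, 0.312 and 0.344. Fragments of open, active promoters, the unequal further inputs to the peak calls and signal of replicate 2 below its calling threshold stay open as explanations. No biological explanation was tested, because the design names none beyond separate pools.

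The second pattern is the CpG-rich kind of those promoters. Unshared promoter peaks had a median GC content of 66.6% in replicate 1 and 52.8% in replicate 2, while shared ones had 58.2 and 57.6%. A GC preference of the library or peak calling of replicate 1 over the whole genome may contribute. Among unshared peaks over 5 kb from every annotated transcript start, the median was 48.9% in 8159 peaks of replicate 1 and 47.2% in 5001 peaks of replicate 2, a difference of 1.70 points (permutation p = 0.0001, the smallest possible, 2-sided). Shared peaks at this distance had a median of 48.7% in either list. The difference thus came from a lower value in replicate 2, and unshared distal peaks of replicate 1 were hardly richer in GC than shared ones. The difference has the predicted sign, but is below the 2 points set beforehand, so the test does not decide. The unshared distal peaks of replicate 1 had GC quartiles of 44.7 and 53%, below the median of 66.6% at promoters. They therefore cannot show a preference that acts on sequence as rich in GC as those promoters, and the explanation stays open.

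The third pattern is the split of the Hox clusters between paralog groups 10 to 13 (11 of 12 genes marked) and 1 to 9 (1 of 27). Annotated 5' ends that are not the promoters in use do not account for it, since with any annotated transcript start 1 of the 27 genes was still marked. CpG-poorer promoters in groups 1 to 9 do not either, with a median ratio of 0.587 against 0.648 and a lower quartile of 0.530 in groups 10 to 13. Of the 27 genes, 4 were marked in at least 1 replicate's own list, so the own lists add few genes to the replicated list. The own lists end at a similar lowest −log10 p (2.00 and 2.05, against 2.05 in the replicated list). They therefore cannot show weaker signal, and whether the peak calling threshold contributes stays undecided. A biological hypothesis is that the sampled tissue lay mostly anterior to the expression domains of groups 10 to 13 and may have expressed groups 1 to 9, which RNA counts of the Hox genes from the same dissected tissue would decide.

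Further values stand without explanation. The peaks with the highest −log10 p in replicate 2 (55.1 and 48.2) lay on chromosome 17 (39843009 to 39846796 and 39847867 to 39848914) over Gm26917, Gm42418, AY036118 and CT010467.1, and their signal values (3.28 and 3.05) ranked at percentiles 40.1 and 21.4 of that list. The X chromosome held 8.85% of the unshared and 2.44% of the shared peaks of replicate 1, and 8.77 and 2.18% of those of replicate 2. Of the genes marked in the replicated list, 19 were marked in neither replicate's own list.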
